A study of Homo sapiens with 12 samples.

How the data were processed

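Messenger RNA was measured in 12 sequencing libraries from KP4 and MiaPaca2, established cell lines derived from human pancreatic ductal adenocarcinoma. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum and received either the solvent DMSO or 100 nM trametinib, an allosteric inhibitor of the kinases MEK1 and MEK2, for 48 h. RNA was purified with a PureLink column kit and made into Illumina libraries with the Tecan Universal mRNA Plus kit, which selects polyadenylated RNA. Each of the 4 groups (KP4 DMSO, KP4 trametinib, MiaPaca2 DMSO and MiaPaca2 trametinib) held 3 libraries, placed in their groups by the sample labels. The labels do not say whether the 3 came from separate cultures, so p-values measure the spread between these samples, which may be technical.

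The authors deposited 1 table of whole-number read counts per gene, with no normalization. Per the submitters' processing notes, STAR, DESeq2 and the GRCh38 (hg38) genome build were used. Tool versions, the counting program, the gene annotation, the use of strand and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies or pseudogenes are therefore uncertain, and a gene cannot be told apart from an overlapping antisense partner. The table held 58735 genes named by Ensembl identifiers, of which 31413 had at least 1 count, with 0 lines that named no gene and 0 columns that matched no sample. All 58735 identifiers were found in GENCODE 29, which gave gene types and GRCh38 positions, and 58207 had a current symbol. Total counts per library ran from 20293688 to 28018129. A group of 3 libraries with 0 counts of a gene allows, at 3 counts over the group, a level of up to 0.0380 CPM (depth-normalised counts) in KP4 DMSO, 0.0365 in KP4 trametinib, 0.0427 in MiaPaca2 DMSO and 0.0432 in MiaPaca2 trametinib. Folds against such groups were computed against these floors and are given as lower bounds. For 1 to 3 counts over a group, the ratio of summed counts is given with its exact 95% interval. Intervals and floors cover counting error only. Counts of the 3 libraries of each group were compared pair by pair with a chi-square test over genes, and no pair agreed within sampling noise, so all 12 libraries were kept as separate samples.

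Genes were filtered with filterByExpr, which left 16133, and scaled with TMM in edgeR 4.0.16 (R 4.3.3, limma 3.58.1, DESeq2 1.42.0). CPM values are TMM-scaled, with a mean and SD over 3 libraries. The main test was edgeR's quasi-likelihood test on a model with 1 mean per group over all 12 libraries, which share 1 estimate of the spread, with robust shrinkage and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called changed. The common dispersion was 0.0029892, a biological coefficient of variation of 5.47%. The contrasts were trametinib minus DMSO in KP4 and in MiaPaca2, the difference between these responses (KP4 minus MiaPaca2), their average, and KP4 DMSO minus MiaPaca2 DMSO. Log2 fold changes are given with their standard error (SE), and n = 3 libraries per group throughout. The fit was tested on simulated counts for the KP4 comparison with 200 changed genes among 15518 tested. edgeR recovered 86% of the 100 genes changed 1.5-fold and 98% of the 100 changed 2-fold, and called 14 unchanged genes in KP4. limma-voom recovered 83% and 97%, DESeq2 84% and 98%. The lysosome list was changed in the simulation as well. Each simulated gene had the same spread in all groups, and most genes were unchanged. In the data 48.1% of genes were called in KP4 and 64% in MiaPaca2, so these rates need not hold there.

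Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested members, which were 32 of 34. In the simulated data the list that had been changed was found, with 0 others. The lists were MAPK output, DNA replication, mitosis, CDK inhibitors and cell cycle exit, ribosome biogenesis, lysosome, V-ATPase, autophagy, iron handling, iron-sulfur clusters, heme synthesis, oxidative phosphorylation, the TCA cycle, glycolysis, cholesterol synthesis, fatty acid oxidation, the integrated stress response, NRF2 and ferroptosis defence, interferon response, antigen presentation, receptor tyrosine kinases and ligands, the BCL2 family, YAP/TEAD targets, ductal, mesenchymal, acinar, neuroendocrine, fibroblast, immune and endothelial markers, classical and basal-like subtype markers, the mitochondrial genome, ribosomal proteins and histones. For each list the number of members past edgeR's test was also counted with p-values adjusted over the list alone.

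Genes named in the text follow a rule. For each contrast it took the 6 largest and 6 smallest log2 fold changes among genes past the test whose libraries did not overlap between groups (not asked of the difference) and whose mean reached 5 CPM in the higher group, leaving out genes without a symbol, clone-named, long intergenic, antisense, divergent, small RNA and pseudogene symbols, and sex-specific genes. It added 31 genes chosen for the MAPK pathway, the cell cycle, lysosome, autophagy and iron, 30 of them tested, and per list and contrast the 2 largest and 2 smallest changes past the test. Chance separates 3 libraries from 3 without overlap in 10% of genes.

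Alternatives were RLE scaling, library size only, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, edgeR's legacy quasi-likelihood fit, no robust shrinkage, limma-voom, DESeq2, a fit on only the libraries compared, a replicate block, leaving out each library in turn, a minimum log2 fold change of 1, an adjusted p under 0.01, camera with an estimated correlation, and fry. Groups, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. Some genes that the rule names are not reported here. No genotype check of the cell lines was possible from counts per gene.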

Results

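Gene expression was measured by poly(A) RNA sequencing in KP4 and MiaPaca2 pancreatic cancer cells after 48 h in DMSO or 100 nM trametinib, with 3 libraries in each of 4 groups. The series asked how transcription in these cells, and above all their lysosomal, autophagy and iron-handling genes, changed when MEK was blocked. For replicates 1, 2 and 3 the total counts were 25105937, 25623155 and 27859186 in KP4 DMSO, 28018129, 26386236 and 26652856 in KP4 trametinib, 24586537, 23799602 and 23207625 in MiaPaca2 DMSO, and 24685087, 20293688 and 24594942 in MiaPaca2 trametinib. Between 21499 and 22720 genes had a count in each library, protein-coding genes held 98.17% to 98.70% of counts, and the 10 most abundant genes held 4.77% to 6.32%. Transcripts of the mitochondrial genome took 4.16% to 4.38% of counts in KP4 DMSO and 5.48% to 5.75% in KP4 trametinib. In MiaPaca2 DMSO that share was 2.35%, 3.32% and 2.25%, and in MiaPaca2 trametinib 4.02% to 4.25%.

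The cell line and then the treatment separated the libraries. In a principal component analysis of all tested genes, the first component held 58.9% of the variance and placed KP4 libraries between −77.1 and −65.5 and MiaPaca2 libraries between 62.1 and 79.3. The second held 27.4% and placed all 6 DMSO libraries at or below −32.1 and all 6 trametinib libraries at or above 32.7. MiaPaca2 DMSO replicate 2 lay at 62.1 on the first component, nearer to KP4 than replicates 1 and 3 at 79.2 and 79.3. Its counts also differed most from those of its own group, with a chi-square per degree of freedom of 15.857 and 14.536 against the other 2 replicates, which differed from each other by 8.331. In the other 3 groups this value ran from 2.032 to 2.965.

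**Figure D1:**
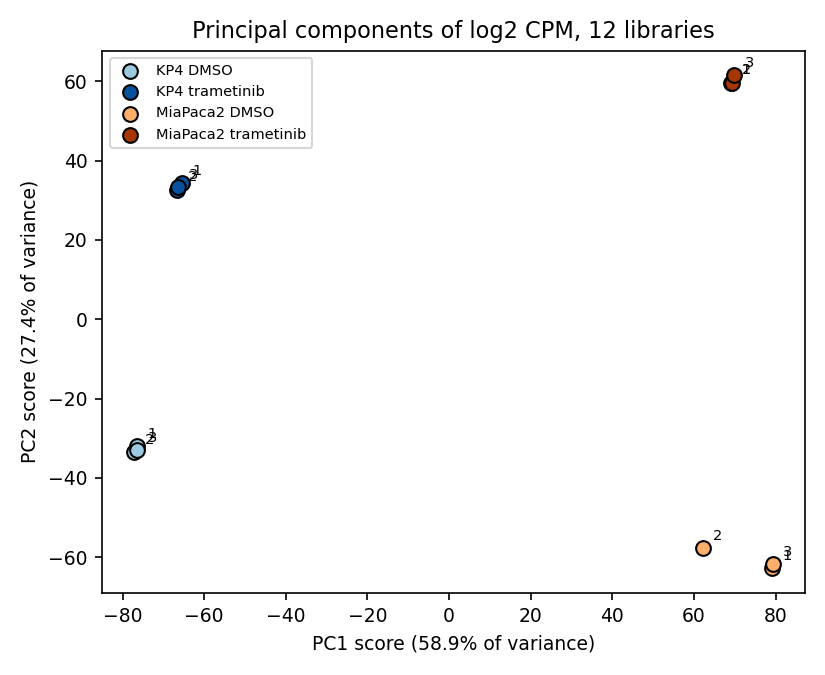
Principal component analysis of the 12 libraries, with the first component (58.9% of variance) on the x axis and the second (27.4%) on the y axis and 1 point per library coloured by group. DMSO and trametinib libraries lie on opposite sides of 0 on the second component, and MiaPaca2 DMSO replicate 2 lies at 62.1 on the first.

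The first comparison asked how KP4 cells responded to trametinib. Transcripts that report ERK activity were among those that fell furthest. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling (ENSG00000187678, chromosome 5, 142310427 to 142326455, GRCh38), fell from 206 ± 3.44 to 2.12 ± 0.132 CPM (mean ± SD, n = 3), a log2 fold change of −6.60 ± 0.08 (SE; edgeR adjusted p = 9.66e-28). DUSP6, the phosphatase that inactivates ERK (ENSG00000139318, chromosome 12, 89347232 to 89353271), fell from 86.0 ± 2.75 to 0.863 ± 0.183 CPM (−6.63 ± 0.29, edgeR adjusted p = 1.24e-08). The ERK-induced transcription factors ETV4 (ENSG00000175832, chromosome 17, 43527844 to 43579620) and ETV5 (ENSG00000244405, chromosome 3, 186046308 to 186110318) fell 115-fold, to 1.08 ± 0.0416 CPM, and from 143 ± 1.93 to 2.22 ± 0.364 CPM. PRSS22, a secreted serine protease, fell by 5.80 on the log2 scale. The collagenase gene MMP1 (chromosome 11, 102789920 to 102798160) fell from 11.5 ± 1.2 CPM to 3 counts over the group, a count ratio of 315 (95% interval 108 to 1531), and its log2 fold change of −8.12 became −8.96 without KP4 trametinib replicate 2.

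Of 32 tested genes of MAPK output in KP4, 30 fell and 1 rose, with a median log2 fold change of −1.92 (camera adjusted p = 4.69e-22). FOSL1, an AP-1 subunit stabilised by ERK, fell from 192 to 75.1 CPM and CCND1, which encodes cyclin D1, from 453 ± 6.06 to 147 ± 5.23 CPM (−1.63 ± 0.05, edgeR adjusted p = 5.69e-20). MYC fell by 0.55 on the log2 scale, to 211 ± 1.22 CPM, and MAP2K1, the gene of MEK1, by 0.36. DNA replication genes fell in 40 of 42 cases (median −0.46, camera adjusted p = 3.50e-16), among them CCNE2 (−0.71) and PRIM1 (−0.65). Among 36 mitosis genes 32 fell, such as UBE2C from 234 to 127 CPM, and 1, KIF20A, rose by 0.19 (median −0.26, camera adjusted p = 3.10e-09; adjusted p = 0.0719 with an estimated correlation). The proliferation marker MKI67 fell from 1219 to 930 CPM. Ribosome biogenesis genes fell in 37 of 40 cases and 3 did not pass the test, with POLR1G at −0.61 and LYAR at −0.56 (median −0.31, camera adjusted p = 1.45e-12). With p-values adjusted over the list alone, the counts lower were 30 for MAPK output, 41 for DNA replication, 34 for mitosis and 37 for ribosome biogenesis. Of 22 CDK inhibitors and cell cycle exit genes, 11 rose and 6 fell (11 and 7 when adjusted over the list alone; camera adjusted p = 0.170), with KLF2 at 2.44, FOXO1 at 1.77 and CDKN1B, which encodes p27, rising from 41.1 to 77.2 CPM.

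Lysosomal and autophagy genes rose as groups in KP4. Of 68 lysosome genes 48 rose and 6 fell (median 0.41, camera adjusted p = 9.86e-09). CTSO, a cysteine cathepsin, rose from 4.78 to 15.2 CPM (1.66 ± 0.12, edgeR adjusted p = 1.42e-11), and the aspartic protease CTSD (0.59 ± 0.05), the membrane glycoprotein LAMP1 (0.39 ± 0.04) and the calcium channel MCOLN1 (0.34 ± 0.08) also rose, while CTSL fell by 0.58. The transcription factor TFEB, a master regulator of lysosomal genes, rose from 14.9 ± 0.832 to 26.7 ± 2.50 CPM (0.84 ± 0.08, edgeR adjusted p = 6.24e-09). Its relative MITF fell by 0.82 and TFE3 was at 0.10 (edgeR adjusted p = 0.0581; past the threshold, at 4.85e-05 to 0.0442, with RLE scaling, library size only, the strict filter, limma-voom, DESeq2, only the libraries compared and without KP4 trametinib replicate 1). Autophagy genes rose in 27 of 58 cases and fell in 6 (median 0.14, camera adjusted p = 2.65e-04). The FOXO target DEPP1 rose by 2.08 ± 0.17 and TP53INP1 by 1.69 ± 0.13 on the log2 scale, and the autophagy receptor gene SQSTM1 rose from 2398 ± 36.9 to 3574 ± 14.8 CPM (0.58 ± 0.13, edgeR adjusted p = 5.38e-03), whereas ATG7 fell by 0.37. Among 21 V-ATPase subunits 8 rose and 2 fell (median 0.14, camera adjusted p = 0.0191; adjusted p = 0.0657 with an estimated correlation), with TCIRG1 at 0.75. That camera p was 0.0581 without KP4 DMSO replicate 2, 0.0582 without trametinib replicate 2 and 0.0624 without trametinib replicate 3. By p-values adjusted over the list alone, the counts higher and lower were 50 and 6 for lysosome, 29 and 6 for autophagy, and 8 and 2 for V-ATPase.

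Iron genes of KP4 moved in both directions. The ferritin genes FTH1 and FTL, whose products store iron, rose from 912 ± 45.1 to 1350.2 ± 10.5 CPM (0.57 ± 0.07, edgeR adjusted p = 6.23e-05) and from 397 to 565 CPM; processed pseudogenes of both exist, so these counts are uncertain. TFRC, the transferrin receptor through which cells import iron, fell from 673 ± 2.76 to 485 ± 4.45 CPM (−0.47 ± 0.04, edgeR adjusted p = 4.17e-11), and the ferrireductase gene STEAP3 fell from 341 to 147 CPM. NCOA4, the receptor for ferritin autophagy, rose by 0.15 and the heme-degrading HMOX1 by 0.89, while FLVCR2 rose by 1.78. The iron regulatory protein genes ACO1 and IREB2 were at −0.22 and 0.24, both past the test. In all, 13 of 33 iron handling genes rose and 13 fell, the same numbers when adjusted over the list alone, and their median (−0.04), mean (0.18) and camera direction (down, adjusted p = 0.969) differed in sign. Iron-sulfur cluster genes fell in 16 of 31 cases and rose in 2 (median −0.18, camera adjusted p = 0.00315), with GLRX3 at −0.49, LIAS at −0.52 and FDXR at 0.42; ISCU was at 0.12 (edgeR adjusted p = 0.0547; past the threshold, at 0.00828 to 0.0496, with the alternatives named for TFE3 and without robust shrinkage) and NFS1 at −0.14 (0.0664, or 0.0348 with only the libraries compared and 0.0409 at −0.18 without trametinib replicate 3). Of 13 heme synthesis genes 7 rose and 1 fell, TMEM14C by 0.60 and ABCB6 by 0.56 among those that rose (median 0.25, camera adjusted p = 0.0397; adjusted p = 0.106 with an estimated correlation). That camera p was 0.0573 without KP4 DMSO replicate 1, 0.0544 without trametinib replicate 2 and 0.0656 with only the libraries compared. Adjusted over the list alone, 3 iron-sulfur genes were higher and 20 lower, and 7 heme genes higher and 1 lower.

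Interferon-stimulated genes showed the largest rises in KP4. IFIT1, which binds viral RNA (ENSG00000185745, chromosome 10, 89392546 to 89406486), rose from 3.54 ± 0.677 to 163 ± 13.3 CPM, 46.2-fold (5.53 ± 0.15, edgeR adjusted p = 6.02e-11). The oligoadenylate synthetase genes OAS1 (ENSG00000089127, chromosome 12, 112906777 to 112933222) and OAS2 rose from 1.31 ± 0.160 to 50.3 ± 3.38 and from 0.225 ± 0.102 to 18.9 ± 1.87 CPM. XAF1 (chromosome 17, 6755447 to 6775647) was at 0 counts in DMSO and 5.07 ± 0.588 CPM in trametinib, at least 133-fold higher (edgeR adjusted p = 1.24e-12). RSAD2, the antiviral enzyme viperin, rose from 3 counts over the group to 5.71 ± 1.03 CPM, a count ratio of 150 (95% interval 51.2 to 732), and the antiviral TRIM22 rose by 6.59 ± 0.37 on the log2 scale. Of 40 interferon response genes 39 rose (median 2.75, camera adjusted p = 1.34e-29), and of 24 antigen presentation genes 18 rose and 6 did not pass the test (median 0.80, camera adjusted p = 9.98e-11), including the MHC class I gene HLA-F from 3.22 to 23.6 CPM and CD74 by 2.80 ± 0.18. With p-values adjusted over the list alone, the counts higher were also 39 and 18; HLA genes are near-identical to each other, so their single values are uncertain.

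Metabolic and stress genes changed in part in KP4. Glycolysis genes fell in 15 of 24 cases and rose in 2 (median −0.27, camera adjusted p = 2.65e-04; adjusted p = 0.341 with an estimated correlation), with the glucose transporter SLC2A3 falling from 194 to 55.3 CPM and hexokinase HK2 by 0.96. Of 22 TCA cycle genes 6 rose, such as IDH1 by 0.55, and 7 fell, such as PC by 0.63 (camera adjusted p = 0.688). Integrated stress response genes fell in 20 of 31 cases and rose in 6 (median −0.39, camera adjusted p = 4.02e-04; adjusted p = 0.341 with an estimated correlation), GDF15 from 37.5 to 2.49 CPM and TRIB3 by 1.21, against a rise of NUPR1 by 2.37. NRF2 and ferroptosis defence genes rose in 17 of 27 cases and fell in 1 (median 0.29, or 0.37 with genes at 0 counts placed at their bounds; camera adjusted p = 2.65e-04), AIFM2 by 1.28 and OSGIN1 by 0.93. By p-values adjusted over the list alone, the counts higher and lower were 2 and 17 for glycolysis, 6 and 7 for the TCA cycle, 6 and 22 for the stress response and 18 and 1 for NRF2 and ferroptosis defence.

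Receptor, survival and YAP/TEAD genes also moved in KP4. Of 37 receptor tyrosine kinases and ligands 16 rose and 9 fell (median 0.26, camera adjusted p = 0.0211; adjusted p = 0.0605 with an estimated correlation), with ERBB4 at 2.42, PDGFRB at 2.26 and MERTK falling from 59.4 to 22.0 CPM. ERBB3 was at 0.27 (edgeR adjusted p = 0.313). In the BCL2 family 6 of 19 genes rose and 7 fell (camera adjusted p = 0.581). The pro-apoptotic BMF and BCL2L11, which encodes BIM, rose by 2.14 ± 0.11 and 0.82 ± 0.07, and the anti-apoptotic BCL2A1 and BCL2 fell, at −3.05 ± 0.22 and −1.62 ± 0.11. YAP/TEAD targets rose in 13 of 22 cases and fell in 4 (median 0.52, camera adjusted p = 0.00621; adjusted p = 0.341 with an estimated correlation), AMOTL2 from 99.1 to 410 CPM and TGFB2 by 2.97, while NT5E fell by 2.16. Adjusted over the list alone, the counts higher and lower were 16 and 9, 6 and 7, and 13 and 4.

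In KP4, 3863 genes rose and 3890 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 48.1% of 16133, and 914 and 472 of them by at least 2-fold. The median log2 change of the called genes was 0.42 in size. Camera placed 19 of 32 lists past its threshold, and 9 with an estimated correlation.

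The second comparison asked the same of MiaPaca2. ERK target genes were again among those that fell furthest: ETV4 from 78.1 ± 2.09 to 0.729 ± 0.493 CPM (−6.72 ± 0.14, edgeR adjusted p = 6.63e-24, and −7.43 without MiaPaca2 trametinib replicate 1), SPRY4 from 229 ± 13.8 to 3.47 ± 0.515 CPM (−6.03 ± 0.08) and ETV5 from 133 ± 3.85 to 2.13 ± 0.751 CPM (−5.93 ± 0.10). DUSP6 fell from 18.3 ± 7.21 to 0.333 ± 0.164 CPM (−5.76 ± 0.50, edgeR adjusted p = 1.97e-06). The transmembrane collagen gene COL13A1 fell by 4.97 ± 0.28, and CASC19, a long non-coding RNA, from 39.2 ± 2.80 to 1.15 ± 0.0227 CPM. Large rises were in IFI44L (ENSG00000137959, chromosome 1, 78619922 to 78646145), an interferon-stimulated gene that went from 0 counts to 25.6 ± 0.629 CPM (at least 599-fold, edgeR adjusted p = 1.89e-19), and IGFN1 (ENSG00000163395, chromosome 1, 201190825 to 201228952), which went from 1 count over the group to 46.5 ± 2.34 CPM, a count ratio of 3274 (95% interval 587 to 129352). The log2 fold change of IGFN1 was 11.24, or 13.20 without MiaPaca2 DMSO replicate 3. ALPG, a placental-type alkaline phosphatase with near-identical paralogs and so uncertain, went from 0 counts to 9.51 ± 1.44 CPM, at least 223-fold higher.

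In MiaPaca2, 24 of the 32 MAPK output genes fell and 8 rose (median −1.35, camera adjusted p = 3.44e-06; adjusted p = 0.119 with an estimated correlation). JUNB rose from 50.5 to 146 CPM and EPHA4 by 1.11; the other 6 risers, named after their values were seen, were FOS (0.62), AREG (0.54), LIF (0.40), IER3 (0.39), TNC (0.37) and ETS2 (0.25). JUNB and FOS encode AP-1 subunits, AREG and LIF secreted ligands, and EPHA4 an ephrin receptor. FOSL1 fell from 187 to 70.3 CPM, CCND1 from 302 ± 24.4 to 203 ± 5.24 CPM (−0.58 ± 0.05, edgeR adjusted p = 3.58e-11) and MYC from 385 ± 31.1 to 186 ± 5.77 CPM (−1.05 ± 0.05, edgeR adjusted p = 2.22e-16). MAP2K1 was at 0.06 (edgeR adjusted p = 0.382) and MAP2K2 at 0.07 (0.239, or 4.43e-04 at 0.17 without MiaPaca2 DMSO replicate 3). DNA replication genes fell in 41 of 42 cases (median −0.84, camera adjusted p = 7.08e-18), with the helicase subunit MCM4 falling from 474 to 195 CPM. Mitosis genes fell in 35 of 36 cases (median −0.75, camera adjusted p = 6.58e-16), PLK1 from 383 to 150 CPM and CDC20 by 1.32. All 40 ribosome biogenesis genes fell (median −0.59, camera adjusted p = 2.22e-16), BOP1 by 1.24 and FBL by 1.11, and MKI67 fell from 1084 to 729 CPM. CDK inhibitors and cell cycle exit genes rose in 14 of 22 cases and fell in 4 (median 0.76, camera adjusted p = 0.0163; adjusted p = 0.179 with an estimated correlation), the anti-proliferative BTG2 from 15.0 to 146 CPM and CDKN1B from 58.1 to 98.7 CPM. With p-values adjusted over the list alone, 24, 41, 35 and 40 genes were lower in the first 4 of these lists and 15 CDK inhibitors and exit genes were higher.

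Lysosome genes rose in 50 of 68 cases in MiaPaca2 and fell in 7 (median 0.45, camera adjusted p = 8.59e-07). CTSS, a cysteine cathepsin, rose by 6.07 ± 0.44 (6.76 without MiaPaca2 DMSO replicate 3) and CTSO from 2.27 to 19.9 CPM, while TPCN1 and DPP7 each fell by 0.52. TFEB rose from 8.44 ± 0.513 to 16.2 ± 0.988 CPM (0.94 ± 0.11, edgeR adjusted p = 2.64e-08), TFE3 by 0.49, LAMP1 by 0.22 and MCOLN1 by 0.60, and MITF was at 0.09 (0.752). CTSD fell by 0.13 (edgeR adjusted p = 0.0258), which became 0.204 at −0.06 without MiaPaca2 DMSO replicate 3, 0.0829 without trametinib replicate 1, 0.0675 without trametinib replicate 3 and 0.0591 with library size only. Autophagy genes rose in 40 of 58 cases and fell in 7 (median 0.45, camera adjusted p = 2.18e-05), the receptor OPTN from 42.9 to 247 CPM and TP53INP1 by 2.27. SQSTM1 rose from 818 ± 190 to 2226 ± 32.2 CPM (1.44 ± 0.13, edgeR adjusted p = 1.01e-05); in DMSO it was at 686 and 731 CPM in replicates 1 and 3 and 1036 in replicate 2, against 2398 in KP4 DMSO. V-ATPase genes rose in 10 of 21 cases and fell in 2 (median 0.15, camera adjusted p = 0.102), TCIRG1 by 1.53 and ATP6V0E1 by 0.95. By p-values adjusted over the list alone, the counts higher and lower were 51 and 8, 40 and 7, and 10 and 2.

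Ferritin, transferrin receptor and heme oxygenase genes of MiaPaca2 changed. FTH1 rose from 619 ± 83.9 to 1256 ± 31.1 CPM (1.02 ± 0.08, edgeR adjusted p = 2.01e-07), FTL from 1968 to 2429 CPM and HMOX1 from 23.8 to 112 CPM, and TFRC fell from 595 ± 32.2 to 382 ± 7.46 CPM (−0.64 ± 0.04, edgeR adjusted p = 4.55e-14). NCOA4 rose by 0.42 and the siderophore-binding LCN2 from 0.214 to 10.9 CPM, while STEAP3, FLVCR1 and ACO1 fell by 1.10, 1.05 and 0.66. IREB2 was at −0.14 (edgeR adjusted p = 0.0809; 0.0350 to 0.0462 with RLE scaling, no filter, the strict filter and DESeq2, and 0.00173 at −0.22 without MiaPaca2 DMSO replicate 2). Of 33 iron handling genes 17 rose and 10 fell, the same when adjusted over the list alone (median 0.23, camera adjusted p = 0.231). Iron-sulfur cluster genes fell in 18 of 31 cases and rose in 4 (median −0.23, camera adjusted p = 0.0194; adjusted p = 0.0606 with an estimated correlation), LIAS by 1.13 and NFS1 by 0.32 against a rise of FDX1 by 0.84. Of 13 heme synthesis genes 5 rose, such as ALAS1 by 0.61, and 3 fell (camera adjusted p = 0.481). Adjusted over the list alone, the counts higher and lower were 4 and 19 for iron-sulfur genes and 5 and 3 for heme genes.

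In MiaPaca2 39 of 40 interferon response genes rose and 1, IFITM2, fell by 0.56 (median 4.64, camera adjusted p = 7.04e-23). TRIM22 (ENSG00000132274, chromosome 11, 5689689 to 5737089) rose from 0.0698 to 101 ± 6.05 CPM (10.37 ± 0.19, edgeR adjusted p = 3.78e-28, and 11.88 without MiaPaca2 DMSO replicate 1). XAF1 rose from 0.131 to 86.3 ± 4.83 CPM (9.34 ± 0.19, and 10.85 without MiaPaca2 DMSO replicate 3), and the chemokine gene CXCL10 from 0 counts to 6.17 ± 1.97 CPM, at least 144-fold. Antigen presentation genes rose in 21 of 24 cases and fell in 1, HLA-DRA by 1.26 (median 2.14, camera adjusted p = 2.25e-10), with HLA-B rising from 51.9 to 1029 CPM and HLA-F by 4.88 ± 0.13. With p-values adjusted over the list alone, the counts were again 39 and 1 and 21 and 1. These changes stood beside a mitochondrial share of 2.25% to 3.32% of counts in DMSO and 4.02% to 4.25% in trametinib.

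Glycolysis genes of MiaPaca2 fell in 19 of 24 cases and rose in 1 (median −0.49, camera adjusted p = 5.04e-06; adjusted p = 0.258 with an estimated correlation), the pyruvate kinase PKM from 3659 to 1676 CPM and SLC2A3 by 1.22, while LDHB rose by 0.80. TCA cycle genes fell in 14 of 22 cases and rose in 4 (median −0.32, camera adjusted p = 0.0106; adjusted p = 0.0529 with an estimated correlation), SUCLA2 by 0.73. Integrated stress response genes rose in 12 and fell in 12 of 31 cases (median −0.08, mean 0.19, camera down with adjusted p = 0.430). NUPR1 rose by 5.16 (5.82 without MiaPaca2 DMSO replicate 3) and ATF3 by 2.37 (2.96 without DMSO replicate 2), while GDF15 fell by 2.10 and ASNS by 1.15. NRF2 and ferroptosis defence genes rose in 16 of 27 cases and fell in 7 (median 0.27, camera adjusted p = 0.126); AKR1C2, whose paralogs are near-identical, was at 6.18, and AIFM2 and GCLM fell by 1.18 and 1.12. By p-values adjusted over the list alone, the counts higher and lower were 2 and 20, 4 and 14, 12 and 13, and 17 and 7.

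Receptor tyrosine kinases and ligands rose in 18 of 37 cases in MiaPaca2 and fell in 9 (median 0.23, camera adjusted p = 0.189, or 0.0496 with no filter), PDGFRB by 3.52 against ERBB3, which fell from 4.49 to 2.28 CPM. The BCL2 family held 11 rises and 6 falls among 19 genes (median 0.28, camera adjusted p = 0.231), with BMF at 2.71 ± 0.15, BCL2L11 at 0.84 ± 0.06 and BCL2 at −1.79 ± 0.15. Of 22 YAP/TEAD targets 16 rose and 4 fell (median 0.88, camera adjusted p = 9.95e-04; adjusted p = 0.287 with an estimated correlation), TGFB2 by 3.20 and IGFBP3 by 2.92, while NT5E fell by 1.83. Adjusted over the list alone, the counts higher and lower were 18 and 9, 11 and 6, and 16 and 4.

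In MiaPaca2, 5545 genes rose and 4785 fell by edgeR's test, 64% of those tested, 2070 and 760 of them by at least 2-fold, and the called changes had a median size of 0.6 on the log2 scale. Without MiaPaca2 DMSO replicate 2, 5628 rose and 4844 fell, and 9771 of the 10330 genes were called the same way, with 0 called the opposite way. The spread was estimated jointly over all groups, although the MiaPaca2 DMSO libraries differed most from each other. Fitted on only the libraries compared, 4772 genes rose and 4674 fell among 15278 tested in MiaPaca2. In KP4 that fit gave 4493 and 4508 among 14954, so the totals of the lines lay nearer to each other than in the joint fit. The lines were also compared within each treatment, on genes at 20 CPM or more in the other line. Under 50% of the KP4 level lay 60 genes in MiaPaca2 trametinib and 391 in MiaPaca2 DMSO. Under 50% of the MiaPaca2 level lay 480 in KP4 trametinib and 474 in KP4 DMSO. Genes were chosen within each treatment, so these counts do not follow the same genes. Fixed genes, unchanged by trametinib in KP4, were also compared between MiaPaca2 trametinib and MiaPaca2 DMSO replicate 1. Those over 4-fold and 2 to 4-fold lower in KP4 DMSO lay at medians of 0.589 and 0.709 of that replicate. Those 2 to 4-fold and over 4-fold higher in KP4 DMSO lay at 1.65 and 1.97. Among these genes the MiaPaca2 levels thus moved towards KP4 in both directions. Camera placed 16 of 32 lists past its threshold, and 7 with an estimated correlation.

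**Figure D2:**
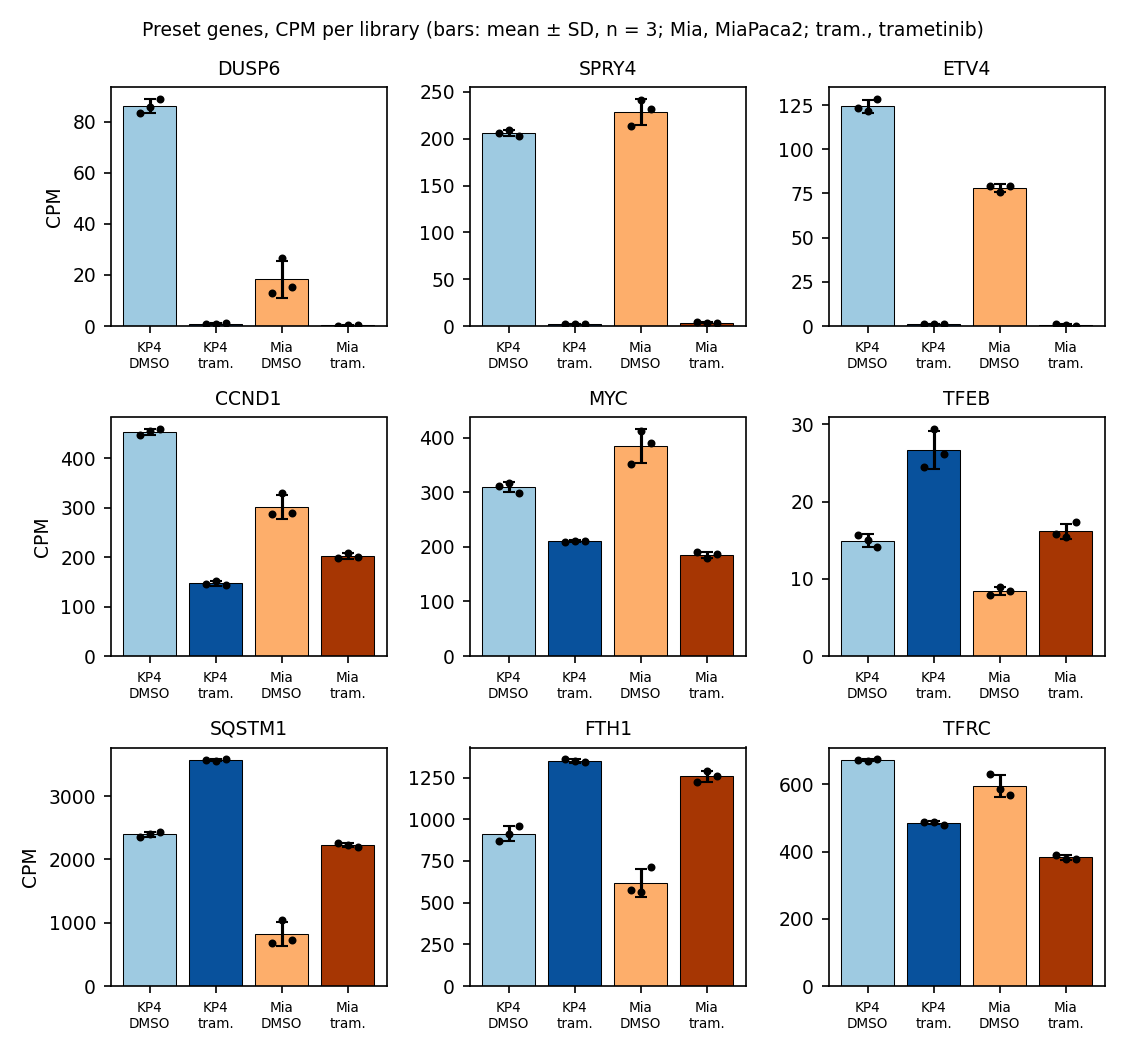
Bars give the mean CPM of 9 genes in the 4 groups, with SD as error bars (n = 3) and 1 point per library; each y axis starts at 0. DUSP6, SPRY4, ETV4, CCND1, MYC and TFRC were lower and TFEB, SQSTM1 and FTH1 higher with trametinib in both lines, and MiaPaca2 DMSO replicate 2 has the highest SQSTM1 point of its group at 1036 CPM.

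Taking both lines together, 3057 genes rose in each of them and 2729 fell in each, against 1327.7 and 1153.8 for independent calls, and 5786 of the 6228 genes called in both lines (92.9%) moved the same way. ETV4, ETV5, SPRY4, DUSP6, FOSL1, CCND1, MYC and TFRC were among the genes lower in both lines. TFEB, SQSTM1, FTH1, HMOX1, CTSO, BMF, IFIT1 and TRIM22 were among those higher in both. Of the genes called in opposite directions, 180 rose in KP4 and fell in MiaPaca2 and 262 did the reverse, where independent calls would give 1145.8 and 1337, and all were past the test of the difference. Across the 16133 genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of 0.626 and a Spearman correlation of 0.61. The average response of both lines was past edgeR's test upwards in 5557 genes and downwards in 4929, 65% of those tested, 1453 and 437 of them by at least 2-fold.

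**Figure D3:**
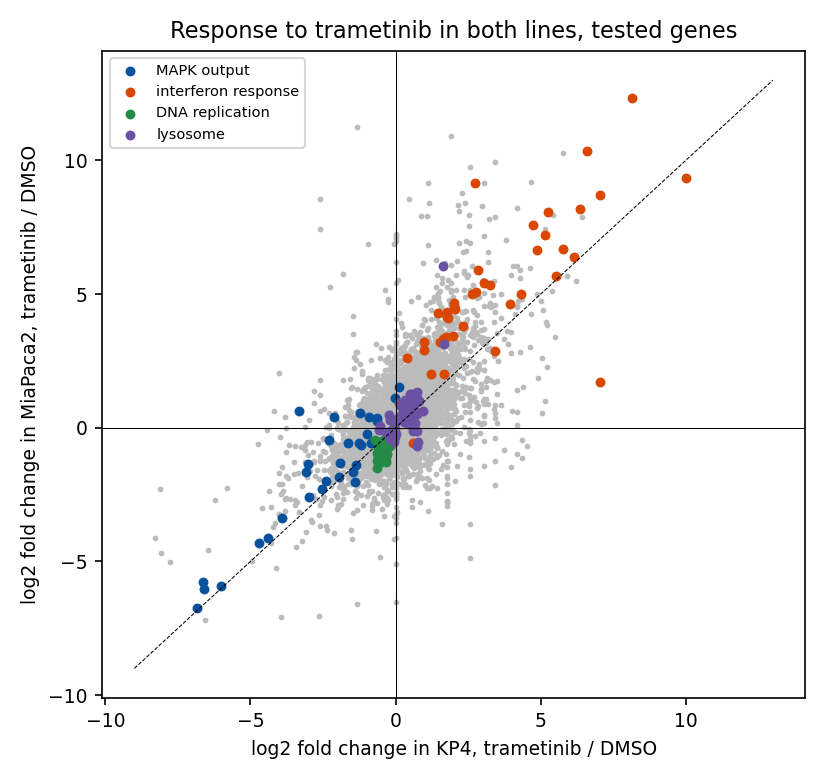
Each point is 1 tested gene, with sex-specific genes left out. The log2 fold change (trametinib over DMSO) in KP4 is on the x axis and that in MiaPaca2 on the y axis. Coloured points are genes of MAPK output, interferon response, DNA replication and lysosome, and the dashed line marks equal change. Most interferon response genes lie above the line, with medians of 2.75 in KP4 and 4.64 in MiaPaca2, and MAPK output genes lie mostly below 0 in both.

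Whether the lines differed in their response was tested as KP4 minus MiaPaca2. A downward difference means that the log2 fold change was lower in KP4. It was downward in 27 of 40 interferon response and 19 of 24 antigen presentation genes and upward in 1 of each, with median differences of −1.98 and −1.24 (camera adjusted p = 3.69e-19 and 5.98e-11). IFI27, an interferon-stimulated gene, went from 0.571 to 3.84 CPM in KP4 and from 0.258 to 149 CPM in MiaPaca2, a difference of −6.41 ± 0.75 (edgeR adjusted p = 1.32e-06). MX2, also interferon-stimulated (ENSG00000183486, chromosome 21, 41361943 to 41409390), went the other way, from 0.0119 to 2.31 CPM in KP4 and from 16.1 to 52.6 CPM in MiaPaca2, a difference of 5.32 ± 0.93 (7.14 without KP4 DMSO replicate 3). Its KP4 DMSO level was 1 count over the group, a count ratio of 182 in KP4 (95% interval 32.4 to 7244), so the fitted difference depends on the prior count. PODXL, a sialomucin of the cell surface (ENSG00000128567, chromosome 7, 131500262 to 131558217), rose from 8.44 to 36.4 CPM in KP4 and fell from 596 to 224 CPM in MiaPaca2 (difference 3.52 ± 0.12, edgeR adjusted p = 3.03e-13). CHI3L2, a chitinase-like protein gene, was at −2.27 in KP4 and 5.26 in MiaPaca2 (difference −7.53 ± 0.59), and KLHDC7B at 0.07 and 5.53 (difference −5.46 ± 0.62).

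For proliferation genes, most of which fell in both lines, the difference was past edgeR's test upwards in 32 of 42 DNA replication genes, 31 of 36 mitosis genes and 30 of 40 ribosome biogenesis genes, the others being not past it, with medians of 0.34, 0.45 and 0.34 (camera adjusted p = 3.40e-13, 1.39e-15 and 1.60e-12). CCND1 fell more in KP4 (difference −1.05, edgeR adjusted p = 2.19e-12) and MYC less (0.50, edgeR adjusted p = 1.28e-06). MAPK output genes differed downwards in 18 of 32 cases and upwards in 2 (median −0.58, camera adjusted p = 5.32e-06; adjusted p = 0.111 with an estimated correlation). Autophagy genes differed downwards in 26 of 58 cases and upwards in 4 (median −0.23, camera adjusted p = 0.00347; adjusted p = 0.0935 with an estimated correlation), with SQSTM1 at −0.87 (edgeR adjusted p = 0.00566). Lysosome genes differed downwards in 29 and upwards in 11 of 68 cases (median −0.18, camera adjusted p = 0.0281, and 0.0537 without KP4 trametinib replicate 1; adjusted p = 0.0521 with an estimated correlation), while CTSD rose more in KP4 (0.72, edgeR adjusted p = 8.40e-09). FTH1, HMOX1 and NCOA4 rose more in MiaPaca2 (−0.46, −1.34 and −0.27) and FTL more in KP4 (0.21). Iron handling genes as a list had 7 upward and 11 downward differences (camera adjusted p = 0.156). With p-values adjusted over the list alone, the counts upwards and downwards were 2 and 27 for interferon response, 1 and 19 for antigen presentation, 2 and 19 for MAPK output, 4 and 28 for autophagy and 11 and 29 for lysosome, and the counts upwards were 36 for DNA replication, 33 for mitosis and 32 for ribosome biogenesis.

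TCA cycle genes differed upwards in 15 and downwards in 2 of 22 cases (median 0.28, camera adjusted p = 3.80e-04), and glycolysis genes in 12 and 2 of 24 (median 0.22, camera adjusted p = 0.00896; adjusted p = 0.494 with an estimated correlation). The BCL2 family (3 and 10 of 19; median −0.38, camera adjusted p = 0.0386), YAP/TEAD targets (2 and 11 of 22; −0.23, 0.0281) and mesenchymal markers (2 and 7 of 15; −0.58, 0.0281) differed downwards, with adjusted p = 0.102, 0.494 and 0.0935 with an estimated correlation. The BCL2 family's camera p was 0.0537 without KP4 trametinib replicate 1, 0.0643 without MiaPaca2 DMSO replicate 2 and 0.0641 without MiaPaca2 trametinib replicate 1. For YAP/TEAD targets it was 0.0511 without KP4 trametinib replicate 1, 0.0665 without MiaPaca2 DMSO replicate 1 and 0.0503 without MiaPaca2 DMSO replicate 3. By p-values adjusted over the list alone, the counts upwards and downwards were 16 and 2, 12 and 2, 3 and 11, 2 and 13, and 2 and 7. In total the log2 fold change was higher in KP4 for 2578 genes and lower for 3186 by edgeR's test (35.7% of those tested), 310 and 838 of them by at least 2-fold. With RLE scaling the numbers were 3055 and 2796, which moved the share higher in KP4 from 44.7% to 52.2%, and with library size only 2500 and 3286.

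**Figure D4:**
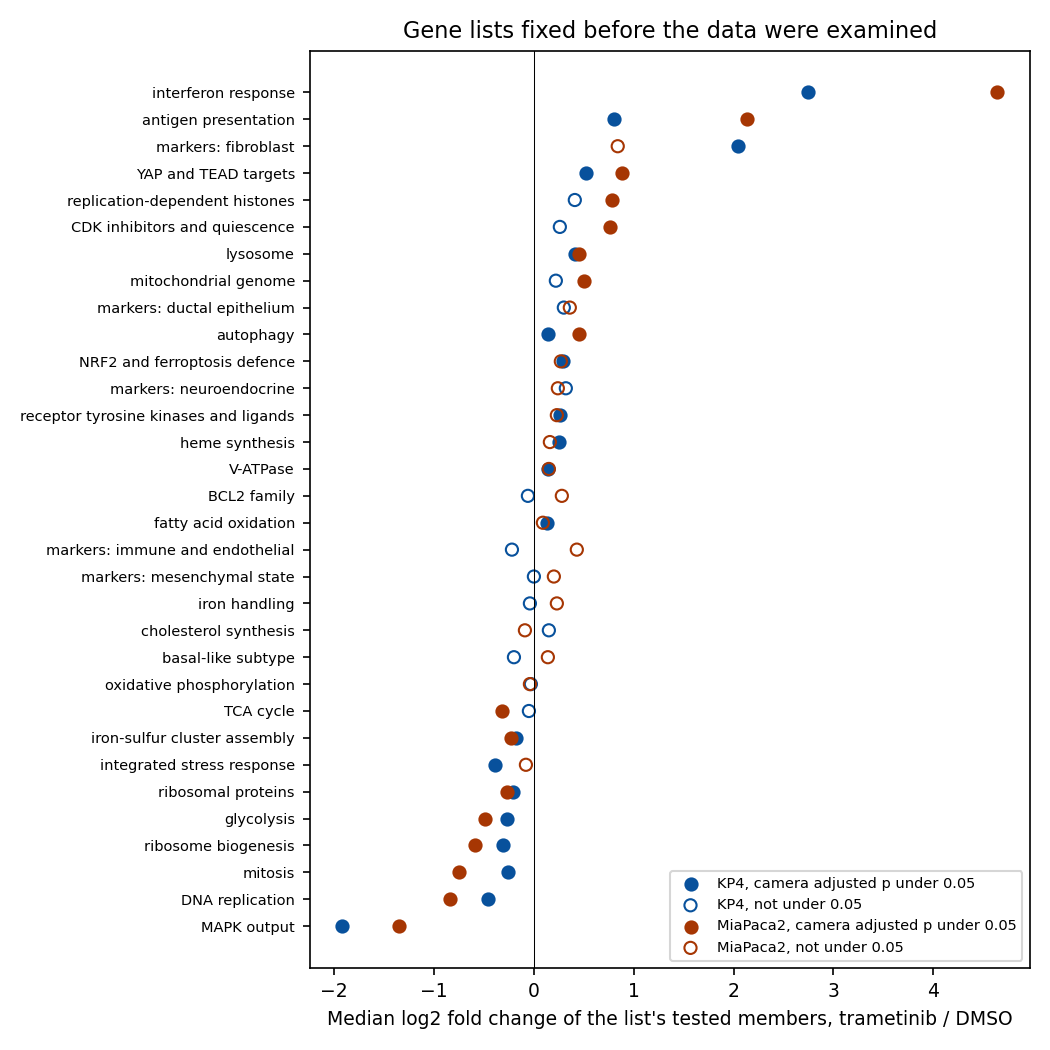
Median log2 fold change (trametinib over DMSO) of the tested genes of each list, with KP4 and MiaPaca2 as separate points; filled points mark lists with a camera adjusted p under 0.05. Interferon response has the highest medians among the lists tested in both lines (2.75 and 4.64) and MAPK output the lowest (−1.92 and −1.35).

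The last comparison set the untreated lines against each other. Genes expressed in MiaPaca2 and at 0 counts in KP4 DMSO included DDIT4L, an inhibitor of mTOR signalling (ENSG00000145358, chromosome 4, 100185870 to 100190782), at 237.6 ± 20.01 CPM in MiaPaca2 DMSO (at least 6250-fold lower in KP4, edgeR adjusted p = 3.73e-25). The proteoglycan gene SRGN (ENSG00000122862, chromosome 10, 69088106 to 69104811), at 193 ± 32.2 CPM, was at least 5085-fold lower and the long non-coding RNA UCA1 at least 3374-fold lower. COL6A3 and COL1A2, which encode collagen chains, were at least 3005-fold and 2646-fold lower, and ADIRF at least 1743-fold. Genes higher in KP4 DMSO had smaller ratios. The cell adhesion gene NRCAM (ENSG00000091129, chromosome 7, 108147623 to 108456717) was at 6.24 ± 0.693 CPM in KP4 and 0.142 ± 0.0641 in MiaPaca2 (5.41 ± 0.34, edgeR adjusted p = 1.66e-13), the stromelysin gene MMP10 (ENSG00000166670, chromosome 11, 102770503 to 102780628) at 38.4 ± 1.06 and 1.15 ± 0.567 CPM (5.05 ± 0.16), and SLITRK4 (ENSG00000179542, chromosome X, 143622790 to 143635777) at 11.8 ± 1.25 and 0.609 ± 0.128 CPM (4.25 ± 0.21). KCNH1, TMEM98 and AUTS2 followed at 4.13, 4.12 and 3.91.

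In all, 5155 genes were higher in KP4 DMSO and 5040 higher in MiaPaca2 DMSO by edgeR's test (63.2% of those tested), 1428 and 1695 of them by at least 2-fold. Among genes at 10 CPM or more in 1 line, 195 of 9380 lay under 10% of the MiaPaca2 DMSO level in KP4 DMSO, and 3 of 9322 under 10% of the KP4 DMSO level in MiaPaca2 DMSO (212 and 4 without MiaPaca2 DMSO replicate 2). In trametinib the numbers were 190 and 2. Without that replicate 5269 genes were higher in KP4 DMSO and 5188 lower, with 9768 of the 10195 called the same way.

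**Figure D5:**
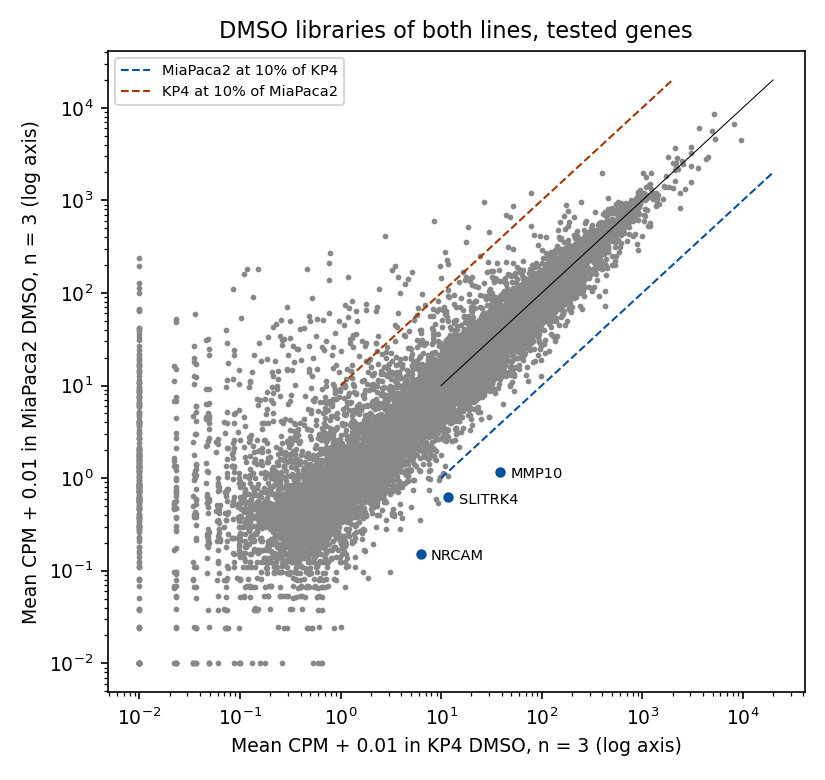
Mean CPM plus 0.01 of each tested gene on log axes, KP4 DMSO on the x axis and MiaPaca2 DMSO on the y axis, with sex-specific genes left out. The dashed lines mark 10% of the other line's level, and MMP10, SLITRK4 and NRCAM are named. Of genes at 10 CPM or more in the higher line, 195 lie beyond the line on the side low in KP4 and 3 on the side low in MiaPaca2; NRCAM, at 6.24 CPM in KP4, is not counted among them.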

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

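Differences between the responses of the lines were tested as planned, and the test of scaling for the interferon genes was chosen only after the result was seen. Each value here is the KP4 minus MiaPaca2 log2 fold change, listed because edgeR or camera placed the difference between the lines past its threshold.

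Among the lists tested, interferon response and antigen presentation had the largest median differences, −1.98 and −1.24, and for the interferon list it stayed at −1.94 or further from 0 with library size only and with RLE scaling. IFI27 differed by −6.41 (edgeR adjusted p = 1.32e-06). MX2 went the other way at 5.32, from 0.0119 to 2.31 CPM in KP4 and from 16.1 to 52.6 CPM in MiaPaca2, and at 7.14 without KP4 DMSO replicate 3. KP4 DMSO held 1 count, a count ratio of 182 in KP4 (95% interval 32.4 to 7244).

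The cell surface gene PODXL differed by 3.52, with a rise in KP4 and a fall in MiaPaca2. TNS4, a focal adhesion gene, differed by 4.09, at −0.06 in KP4 (edgeR adjusted p = 0.952) and −4.15 in MiaPaca2. CHI3L2 differed by −7.53 and KLHDC7B by −5.46. MMP1 fell in both lines and further in KP4 (−5.84, and −6.69 without KP4 trametinib replicate 2). IGFN1 differed by −12.57 on 3 counts in KP4 DMSO and 1 in KP4 trametinib, too few for a fold, against a count ratio of 3274 in MiaPaca2 (95% interval 587 to 129352); the value was −11.71 without KP4 DMSO replicate 2 (edgeR adjusted p = 0.0457), −14.34 without KP4 trametinib replicate 3 and −14.53 without MiaPaca2 DMSO replicate 3.

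A further 4 genes were near 0 in KP4, so their differences rest on few counts there. RSPO4, a WNT agonist, differed by 5.21 (edgeR adjusted p = 0.0394), which became 0.0808, 0.0818 and 0.0860 without KP4 DMSO replicates 1, 2 and 3, 0.0664 without KP4 trametinib replicate 1, and 0.196 at 4.26 without KP4 trametinib replicate 3. GABBR2, a GABA receptor subunit gene, differed by 4.23 (edgeR adjusted p = 0.0445), which became 0.808 at 0.57 without KP4 trametinib replicate 1, 0.0904, 0.0710 and 0.0747 without KP4 DMSO replicates 1, 2 and 3, 0.0513 without MiaPaca2 DMSO replicate 3, and 0.0571 and 0.0531 without MiaPaca2 trametinib replicates 1 and 3. TMEM179 differed by 3.67 (edgeR adjusted p = 0.0174), 3.10 without KP4 DMSO replicate 3 (0.0543), 2.73 without KP4 trametinib replicate 3 (0.232) and 4.53 without KP4 DMSO replicate 2. The cytidine deaminase gene CDA differed by −6.06 (edgeR adjusted p = 0.0157) and by −5.13 without KP4 DMSO replicate 2 (0.130). In KP4 the counts went from 2 to 5 for GABBR2 (count ratio 2.40, 95% interval 0.393 to 25.2) and from 3 to 9 for TMEM179 (2.88, 0.719 to 16.5), intervals that include 1. The fitted values of RSPO4 and CDA set a KP4 group at 0 counts against another and, like those of GABBR2, TMEM179, MX2 and IGFN1, depend on the prior count.

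Upward medians were 0.34 for DNA replication, 0.45 for mitosis, 0.34 for ribosome biogenesis, 0.28 for the TCA cycle and 0.22 for glycolysis (for glycolysis adjusted p = 0.494 with an estimated correlation). Ribosomal proteins were at 0.07 (camera adjusted p = 0.0202, 0.208 without MiaPaca2 DMSO replicate 3 and 0.0750 without MiaPaca2 trametinib replicate 1; adjusted p = 0.707 with an estimated correlation), from 16 upward and 3 downward differences among 75 genes, the same when adjusted over the list alone. Downward medians were −0.58 for MAPK output, −0.18 for lysosome, −0.23 for autophagy, −0.38 for the BCL2 family, −0.23 for YAP/TEAD targets and −0.58 for mesenchymal markers. With an estimated correlation these had adjusted p = 0.111, 0.0521, 0.0935, 0.102, 0.494 and 0.0935. Of the 14 lists past camera's threshold for the difference, 6 were past it with an estimated correlation.

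Of the 30 preset genes tested, 18 differed between the lines. In the MAPK pathway and cell cycle the differences were −0.41 for MAP2K1, −0.57 for SPRY4, −1.05 for CCND1, 0.50 for MYC, 0.18 for MKI67 and 1.27 for the receptor gene ERBB3. Lysosome and autophagy genes differed by −0.39 for TFE3, −0.91 for MITF, 0.17 for LAMP1, 0.72 for CTSD and −0.87 for SQSTM1. Iron genes differed by −0.27 for NCOA4, −0.46 for FTH1, 0.21 for FTL, 0.17 for TFRC, −1.34 for HMOX1, 0.44 for ACO1 and 0.38 for IREB2.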

How the results depend on the processing

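Under the other scalings, filters, fits and tools, the replicate block and each left-out library, 284 of 315 results for named genes kept their direction and their side of the threshold, 26 lost a call in at least 1, 5 gained one and 0 reversed. For 96 list medians with camera's preset correlation these numbers were 76, 8, 12 and 0. Camera works on log2 CPM, so with the legacy fit, no robust shrinkage, limma-voom and DESeq2 its result could not change. With those alternatives only the sign of a median could. Of the same 96 list tests 27 lost their call with an estimated correlation, and under fry 23 gained one, 1 lost it and 1 reversed. The minimum fold and the adjusted p under 0.01 were applied to counts of genes, not to single genes or lists. RLE scaling, library size only, the filters, the other fits, limma-voom and DESeq2 kept each count of called genes within 1.5 times the reported one. Requiring a 2-fold change left 914 and 472 genes in KP4, 2070 and 760 in MiaPaca2, 310 and 838 for the difference, 1453 and 437 for the average, 675 and 198 in both lines, and 1428 and 1695 at baseline. Lists past camera's threshold went from 19 to 9 in KP4, 16 to 7 in MiaPaca2 and 14 to 6 for the difference with an estimated correlation; the cause was not tested. Fry, which does not compare a list with other genes, gave 27 in MiaPaca2, and turned the ductal list in KP4 from up to down with an adjusted p of 1.12e-05. The correlation between the lines was 0.659 among genes called in either line, 0.669 with the strict filter, and 0.582 to 0.616 when 1 library was left out. Leaving out 1 library gave 3412 to 3689 genes higher and 3134 to 3494 lower in KP4, 5209 to 5628 and 4500 to 4844 in MiaPaca2, 2292 to 3031 and 2427 to 3712 for the difference, 5255 to 5722 and 4757 to 5072 for the average, 2725 to 3149 and 2376 to 2900 in both lines, and 4836 to 5269 and 4723 to 5188 at baseline, with 16525 to 16612 genes tested. Depth limited genes at 0 counts in a group to the floors of 3 counts, so their folds are bounds.

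With the replicate block, 3764 genes were higher and 3780 lower in KP4 and 5489 and 4735 in MiaPaca2; of 96 list tests 3 lost a call and 1 gained one, and of 315 results for named genes 6 lost one. Within a line, same-numbered libraries did not deviate together. The correlations of their deviations from the group means ran from −0.024 to 0.021 over the 6 pairs of a DMSO and a trametinib library, 3 in each line. Of these 6, 1 correlated best at its own number. Across the lines they ran from 0.008 to 0.033, and 5 of 6 pairs, the 3 of DMSO among them, correlated best at their own number. No correlation was over 0.1, so the numbers were not taken to pair the libraries, though a weak deviation shared across the lines was not excluded.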

Other observations

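The tests of mixed RNA, of trametinib exposure, of shared libraries and of neighbours among genes lowest in MiaPaca2 were chosen only after the results were seen; those of neighbours among genes low in KP4, interferon transcripts and regrouped libraries were set beforehand.

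In KP4 the epithelial cadherin gene CDH1 rose from 0.472 to 4.96 CPM (3.39 ± 0.24, edgeR adjusted p = 6.69e-12) while the ductal transcription factor gene SOX9 fell from 126 to 27.2 CPM (−2.21 ± 0.05) and CLDN4 by 2.00; in MiaPaca2 CDH1 rose by 3.95 ± 0.41 and MUC1 by 2.70 ± 0.08, and KRT18 and SOX9 fell by 1.80 and 1.54. Of 13 ductal markers 5 rose and 3 fell in KP4 (camera adjusted p = 0.702, up, where fry gave down) and 6 rose and 5 fell in MiaPaca2 (0.903; median 0.36 and mean 0.38 against a camera direction of down). Of 15 mesenchymal markers 4 rose and 6 fell in KP4 (camera adjusted p = 0.214; median 0.00, or 0.17 with genes at 0 counts at their bounds, and mean −0.05), SNAI1 by 1.08, and 8 rose and 7 fell in MiaPaca2 (0.946; median 0.20, mean 0.52, camera down), where SNAI2 rose by 4.05 ± 0.23 and TGFBI fell by 1.55. GATA6, a marker of the classical subtype, rose by 0.44 in KP4 and 1.07 in MiaPaca2 and FOXA2 fell by 1.32 and 0.76; with 4 genes tested, 1 up and 2 down in each line, that list had no test. Basal-like markers held 2 rises and 6 falls among 14 genes in KP4 (camera adjusted p = 0.172) and 6 and 5 in MiaPaca2 (0.902; median 0.14, mean −0.18), SCEL falling by 2.28 and 2.03. Fibroblast markers rose in 5 of 10 cases in KP4 (camera adjusted p = 0.0183; adjusted p = 0.104 with an estimated correlation; median 2.04, or 0.48 with 4 genes at their bounds), and rose in 8 and fell in 2 in MiaPaca2 (0.113, or 0.00980 with no filter), PDGFRB by 2.26 and 3.52, against a fall of COL6A3 from 114 to 26.1 CPM in MiaPaca2. Neuroendocrine markers (3 up and 4 down of 10 in KP4, 3 and 3 in MiaPaca2; camera adjusted p = 0.802 and 0.903, down against medians of 0.32 and 0.24) included falls of SCG2 by 1.76 and 2.26. Immune and endothelial markers had 1 up and 1 down of 7 in KP4 (0.969; median −0.22, mean 0.21) and 2 and 3 in MiaPaca2 (0.698; median 0.43, mean −0.41), and of 4 acinar genes 1, NR5A2 at 0.67 in MiaPaca2, passed edgeR's test in either line. Fry, which does not compare a list with other genes, also called mesenchymal and basal-like markers down in KP4 (adjusted p = 4.25e-08 and 3.47e-05), and in MiaPaca2 ductal and neuroendocrine markers down (3.23e-06 and 0.0468) and fibroblast markers up (1.54e-05). Adjusted over the list alone, each of the counts of markers was the same.

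Fatty acid oxidation genes rose in 8 of 22 cases in KP4 (median 0.13, camera adjusted p = 0.0184; adjusted p = 0.341 with an estimated correlation) and rose in 10 and fell in 4 in MiaPaca2 (0.189), where CPT1A, the gatekeeper of mitochondrial fatty acid import, rose by 0.88 ± 0.04 (edgeR adjusted p = 2.58e-16). Cholesterol synthesis genes were 9 up and 4 down of 24 in KP4 (camera adjusted p = 0.148, or 0.0153 with only the libraries compared), LSS at 0.90, and 7 and 7 in MiaPaca2 (0.614; median −0.09, mean 0.06), FDPS at −0.73. Oxidative phosphorylation genes were 6 up and 13 down of 75 in KP4 (camera adjusted p = 0.395), UQCRH at −0.54, and 13 and 29 in MiaPaca2 (0.112, but 0.0280 with no filter, 0.0131 without MiaPaca2 DMSO replicate 2 and 0.0382 without trametinib replicate 2), CYC1 at −0.79. Mitochondrial genome transcripts rose in 3 of 13 cases and fell in 1 in KP4 (0.171, or 0.00671 with only the libraries compared), MT-ND3 by 0.27, and rose in 10 in MiaPaca2 (median 0.50, camera adjusted p = 0.0275, 0.0733 without DMSO replicate 1 and 0.0510 without DMSO replicate 3; adjusted p = 0.620 with an estimated correlation). Ribosomal protein genes, which have many pseudogene copies, fell in 50 of 75 cases in KP4 and fell in 58 and rose in 1 in MiaPaca2 (medians −0.21 and −0.27, camera adjusted p = 4.54e-08 and 1.66e-08; adjusted p = 0.341 and 0.328 with an estimated correlation). Histone genes, near-identical to each other, rose in 12 and fell in 2 of 28 cases in KP4 (median 0.41, camera adjusted p = 0.0535, or 0.0202 to 0.0334 with no filter, the strict filter and only the libraries compared) and in 14 and 6 in MiaPaca2 (median 0.78, camera adjusted p = 0.0357, 0.0709 without DMSO replicate 3, 0.0540 and 0.0797 without trametinib replicates 1 and 2; adjusted p = 0.301 with an estimated correlation). The histone genes tested were the replication-dependent ones. The kit selects polyadenylated RNA, so histone transcripts without a poly(A) tail were not covered, and the values do not stand for all histone mRNA. With p-values adjusted over the list alone, counts differed in KP4 for oxidative phosphorylation (5 and 13), the mitochondrial genome (2 and 1) and ribosomal proteins (55 lower), and in MiaPaca2 for histones (15 and 7).

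MiaPaca2 DMSO replicate 2 lay towards KP4 on the first principal component. Partial exposure of that culture to trametinib was argued against but not excluded. The 24 MAPK output genes that fell in MiaPaca2 lay at a median 0.15 higher on the log2 scale in that library than in replicates 1 and 3. Of these, 18 were higher, and interferon response genes lay at −0.02. The 24 were called with that library among the DMSO libraries, which favours genes high in it. Its SQSTM1 level (1036 CPM against 686 and 731) and mitochondrial share (3.32% against 2.35% and 2.25%) lay towards trametinib, and also towards KP4. KP4 RNA at a share of 17.5% or more, the lower limit of what genes over 4-fold lower in KP4 would need, was argued against: 10 of 10492 transcripts (3 with bounds corrected for the number of transcripts) lay below that share of their KP4 level, and 14, 46 and 123 lay under 20%, 30% and 40%. A smaller share could not be excluded. The 172 transcripts specific to MiaPaca2 lost 22.5% (95% interval 21.2 to 23.7). By contrast, 54 high in KP4 gained 11.4% of their KP4 level (9.51 to 13.8). MMP10, SLITRK4 and NRCAM lay under 10% in this library and in replicates 1 and 3. These 3 transcripts argue against shares from 10% up, though 5 had been set as decisive. The 4 classes of baseline ratio gave shares of 19.3%, 18.8%, 18.8% and 11.5%, the lowest 0.596 of the highest. That ratio lay between limits of 0.25 and 0.75, set after the first of these values had been seen. No biological explanation was tested, because the design names none for a single library.

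Genes under 10% of the other line's level were nearly all low in KP4 DMSO, 195 against 3 in MiaPaca2 DMSO, and 94 of the 195 were under 1%. Lost or silenced stretches of chromosome in KP4 are a candidate explanation: among 180 such protein-coding genes 19 pairs were neighbours, 5.39 times the mean of 3.53 among random genes of 10 CPM or more in MiaPaca2 (permutation p = 0.0001, the smallest that 10000 draws can give), though the longest run of neighbours was 3 genes. The 180 genes lowest in MiaPaca2, at up to 35.6% of their KP4 level, held 14 pairs, 3.94 times the mean of 3.55 among random genes of 10 CPM or more in KP4 (permutation p = 0.0001). Taken instead from genes of 10 CPM or more in MiaPaca2, as many genes held 8 pairs, 2.27 times the mean of random draws. Neighbouring was above the random mean in each set, and most so in genes low in KP4. By itself it does not set lost stretches apart from other differences between the lines. KP4 RNA could lie at a share of 10% or more in every MiaPaca2 DMSO library. Each transcript would then keep at least that share of its KP4 level. In each library 3 of 10492 KP4 transcripts, MMP10, SLITRK4 and NRCAM, had upper counting bounds under 10%. They lay at or under 4.66%, 6.31% and 3.42% of their KP4 level. MMP10 was at 0.949, 1.79 and 0.709 CPM in these libraries, against 38.4 CPM in KP4 DMSO. These 3 argue against such a share of KP4 RNA with the profile measured here. It was not excluded, as 5 transcripts had been set as decisive. Expression that differs between the lines for other reasons stays open and untested.

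The MiaPaca2 response correlated weakly with the baseline difference between the lines. The Pearson correlation across 10900 genes was 0.24, or 0.28 with DMSO libraries 3 and 1 kept apart, against 0.10 so measured for the KP4 response. Noise of single MiaPaca2 DMSO libraries shared by both measures was excluded as the whole cause: the correlation was 0.29, 0.16 and 0.30 with the same library in both and 0.14 to 0.28 over the 6 pairs of separate libraries, which kept at least 0.88 of it (the limit of 0.5 replaced, after the values were seen, a first limit of 0.3 for the correlation, which no more than the highest shared value reached). More KP4 RNA in the MiaPaca2 trametinib libraries, at a share of 36.3% or more, was argued against by the same measure: 17 of 10639 transcripts (9 with corrected bounds) lay below it in each library. In each library 5, 10 and 23 transcripts lay under 20%, 30% and 40%, where 5 had been set as decisive. Shares from 20% up were thus also argued against, though those bounds were not corrected for the number of transcripts. A share under 20% could not be told apart from a response of the cells. The 4 classes of genes unchanged in KP4 gave larger shares, of 46.4%, 51.3%, 46.9% and 30.4%. The lowest was 0.593 of the highest, between the limits of 0.25 and 0.75. At the lowest share that these classes allow, 13.5%, 1 transcript, NRCAM at 4.74%, lay below it. Among 5493 genes within 0.25 (log2) of each other at baseline, 3477 (63.3%) were called in MiaPaca2 and 2255 the same way in both lines.

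Interferon made by the treated cells is a candidate explanation for the rise of interferon response genes. Summed over 21 interferon genes, counts went from 1 to 13 in the KP4 libraries (ratio 12.5, 95% interval 1.88 to 531, exact conditional p = 0.00188) and from 6 to 78 in the MiaPaca2 libraries (13.2, 5.78 to 37.0, p = 1.70e-17). IFNB1 went from 1 to 5 counts in KP4 and from 0 to 28 in MiaPaca2, IFNL1 from 0 to 0 and 3 to 15, IFNL2 from 0 to 4 and 0 to 12, and IFNL3 from 0 to 4 and 3 to 23; the other 17 genes had 0 counts. IFNL2 and IFNL3 are near-identical, so their single counts are uncertain, and reads pooled over 3 libraries carry counting error only. Secreted protein and its order in time were not measured.

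Other groupings of the libraries were counted for each total. For KP4, MiaPaca2 and the DMSO baseline, the 6 libraries make 10 splits, too few for a share under 0.05; the real split called 7753, 10330 and 10195 genes by edgeR and the highest of the others 0 in each case (273, 914 and 690 at an unadjusted p under 0.05), so that 1 of 10 was as large. For the average response 1 of 100 splits was as large (10486 genes, highest other 6456). For genes called the same way in both lines 1 of 100 was as large (5786, highest other 0, or 188 at an unadjusted p under 0.05). Both shares were under 0.05. Splits that mix DMSO with trametinib libraries put the treatment effect into the spread and so call fewer genes. The real grouping thus stood out, but these counts do not exclude chance differences between cultures. For the difference between the responses 7 of 100 splits called as many genes (5764, highest other 6377), so chance was not excluded by this count. All 6 of those other splits kept the real grouping of 1 line, as 20 of the splits did, and so carried that line's response into the difference. Splits that kept neither line's grouping called at most 0 genes by edgeR. The count for the difference could therefore not decide the question.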
